A study of Mus musculus with 6 samples.

How the data were processed

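Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with biotin-labelled cRNA made from total RNA of mouse embryonic stem cells of a 129/B6 hybrid background, per the labels' protocols. The arrays come from 3 cell clones. Clone 3031 carries wild-type Yaf2 (Yaf2wt), and clones 3086 and 3087 carry a Yaf2 knockdown (Yaf2kd). Each clone gave 1 array with 4-hydroxytamoxifen (OHT+) and 1 array without it (OHT-). To deplete Rybp, the OHT+ cells received 4-hydroxytamoxifen at 0.8 µM over 24 hours, per the labels' protocols. The time between treatment and harvest is not given in the sources used here. The cultures grew with leukaemia inhibitory factor, and either feeder fibroblasts or gelatin served as the surface; which surface each sample had is not given. The groups hold 1 array each for Yaf2wt OHT+ and Yaf2wt OHT-, and 2 arrays each for Yaf2kd OHT+ and Yaf2kd OHT-. The labels make the Yaf2kd replicates separate clones, so p-values measure only the spread between these samples.

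The deposited values are probe-set intensity values, and the submitters' processing notes name Affymetrix Expression Console and RMA; the role and version of each are not given in the sources used here. The values were tested for their scale: they run from 0.140 to 45795 with a median of 102, all are above 0, and every array holds the same sorted values, which is what quantile normalization leaves. They were therefore taken as linear intensity, where the plan had assumed log2 expression, and the log2 of the deposited intensity was used with no pseudocount. The series text names a 430A 2.0 array, whereas the table holds 45101 probe sets; the annotation of those 45101 was used. Depth in counts has no meaning for these arrays, and the number of arrays limits the precision. The signal over background also limits it: the median replicate standard deviation (log2) was 0.70 for the lower 40% of genes by mean signal and 0.16 for the other genes.

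Of the 45101 probe sets, 34958 were annotated to 1 gene symbol, 932 to several symbols and 9211 to no gene in the annotation. The brightest probe set by mean over the 6 arrays stood for each gene, which gave 18194 genes, 9012 of them with several probe sets. The gene identifiers matched the mouse gene reference (assembly GRCm38.p6, used for names only) for 99.4% of the probe sets annotated to 1 symbol. Both Rybp probe sets are annotated to Rybp and to the pseudogene Rybp-ps together, so they are not in the gene table and are reported as probe sets.

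The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Each gene was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all 18194 genes and a threshold of 0.05. The OHT effect over the 3 clones came from a model of Yaf2 status and OHT on all 6 arrays, with 3 residual degrees of freedom. The OHT effect in Yaf2kd cells, the Yaf2 effect without and with OHT, the combined loss (Yaf2kd OHT+ against Yaf2wt OHT-) and the difference of the OHT effects came from a model of the 4 groups, with 2 residual degrees of freedom. In that model the lone Yaf2wt arrays are assumed to vary like the Yaf2kd groups. The Yaf2wt pair of arrays has no replicate: its genes were ranked by size and its list medians placed among 10000 random lists of the same size and similar mean signal, with limma on a spread pooled from the Yaf2kd groups as an alternative. The Yaf2 effects compare the 2 Yaf2kd clones with a single Yaf2wt clone, so Yaf2 status and clone identity cannot be told apart.

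The 21 gene lists were preimplantation and 2-cell-stage genes, germline and meiosis genes, Polycomb-bound developmental regulators, subunits of Polycomb repressive complexes 1 and 2 (PRC1 and PRC2), DNA methylation and H3K9 methylation machinery, pluripotency genes, epiblast and primed-state genes, primitive endoderm genes, mesoderm and primitive streak genes, neuroectoderm genes, trophectoderm and placenta genes, p53 targets, interferon-response genes, sterol biosynthesis genes, fibroblast markers for a feeder layer, cell cycle genes, imprinted genes, X- and Y-linked clone identity genes, hypoxia and glycolysis genes, stress-response and unfolded-protein genes, and control genes. They came from general knowledge of these classes, and whether any member was first picked from these samples is not known. Of 611 list entries 557 were measured. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists of a comparison; an estimated correlation and fry were alternatives.

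The rule for named genes took Rybp and Yaf2, then up to 10 genes in each direction that passed with every array or clone on the same side. Where fewer than 10 passed, the largest differences under the same condition on arrays or clones filled up to 5, given as values that did not pass. Each list gave up to 4 members in the OHT effect over the 3 clones and up to 2 in each other comparison in which the list or a member was called. The Yaf2wt pair gave its 10 highest and 10 lowest genes among those with the higher array above the median of all genes. Genes named from fits other than that over all genes were chosen after their values were seen.

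Results were recomputed under settings fixed in advance: the clone as a block, median centring, further quantile normalization, leaving out the 40% of genes with the lowest mean (below an intensity of 106, leaving 10916 genes), the mean of all probe sets, no probe sets of the _x_at or _s_at kind, an intensity trend or robust option in eBayes, no moderation, a 1.5-fold minimum, and leaving out each array or clone. A pseudocount of 16, and combinations with the dim genes left out, were added after seeing the data. The limma steps were tested on simulated arrays with 200 changed genes of higher signal in each of 5 runs. For the OHT effect over the 3 clones, the fit on 18194 genes recovered 0.2% of 2-fold and 71.0% of 4-fold changes. With the dim genes left out (10916 genes) it recovered 78.6% and 94.2%, and with the intensity trend (18194 genes) 83.6% and 99.4%. False calls made up 5.07%, 5.05% and 7.58% of the calls of these 3 fits. For the Yaf2 effect without OHT, the fit on 18194 genes recovered 0% of either size, and that on 10916 genes recovered 5.2% of 2-fold and 80.6% of 4-fold changes. The fit with the intensity trend recovered 58.4% and 87.8%, and 7.00% of its calls were false. For the OHT effect in Yaf2kd cells the fit on 18194 genes recovered 0% of either size, and that on 10916 genes 41.0% and 92.6%. With the intensity trend the recovery was 72.2% and 97.2%, and 8.23% of the calls were false. The simulated spread of each gene was shrunk towards a trend with mean signal, which is the form that the intensity trend assumes. No difference between clones was simulated. These runs can therefore flatter the fits, above all that with the trend, and do not show how many real calls are true. A simulated list that was raised was found by camera in 20 of 20 runs with either correlation, and 0 other lists were called. In these runs the genes varied independently and every member was raised by the same amount. The runs therefore do not show how camera performs on lists of correlated genes.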

Results

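Expression was measured on 6 arrays from 3 mouse embryonic stem cell clones, each with and without 4-hydroxytamoxifen (OHT), given to deplete Rybp per the labels. Rybp and its homologue Yaf2 are subunits of Polycomb repressive complex 1. Clone 3031 has wild-type Yaf2 (Yaf2wt, 1 array per condition), and clones 3086 and 3087 are Yaf2 knockdowns (Yaf2kd, 2 arrays per condition). The values are linear intensity after normalization, compared as log2 over 18194 genes. The median intensity was 102 on every array, and the ratio of the 3' to the 5' control probe sets lay between 0.801 and 0.832 for Gapdh and between 1.31 and 1.44 for Actb. No batch or hybridization date is given in the labels.

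The targeted genes were read on each array. Both probe sets for Rybp are annotated to Rybp and its pseudogene Rybp-ps together, and they moved in opposite directions with OHT. The probe set that is lower with OHT was at 2014 ± 239 (SD, n = 3) without OHT and 85.8 ± 27.7 with it. The other was at 242 ± 82.4 without OHT and 3162 ± 332 with it. Their log2 differences were -4.61 ± 0.68 and 3.75 ± 0.61 (SD over 3 clones), with the same direction in all 3 clones. The second is a 13.5-fold higher signal. The size of the first is uncertain, since its signal lay below the limit of 106 for dim genes on each OHT+ array. The same holds for every gene that is dim in a compared group, with a mean there under that limit. In a limma fit over all probe sets other than controls, in place of genes, the adjusted p was 0.296 for both. With an intensity trend it was 1.1e-04. Which part of the gene each probe set covers is not given in the sources used here. They therefore separate OHT+ from OHT- arrays without measuring how much intact Rybp RNA was left. The brightest Yaf2 probe set was at 276 ± 27.2 in the Yaf2kd arrays (n = 4) and 793 ± 33.6 in the Yaf2wt arrays (n = 2), and the other at 237 ± 18.1 and 629 ± 40.2. The Yaf2kd arrays thus held 34.8% and 37.7% of the Yaf2wt signal. The limma difference of Yaf2 was -1.63 ± 0.24 (SE) without OHT, -1.42 ± 0.24 with OHT and -1.51 ± 0.24 in the combined loss, and none of these 3 passed the adjustment. OHT itself left Yaf2 at 0.0539 ± 0.14 (log2) over the 3 clones.

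**Figure D1:**
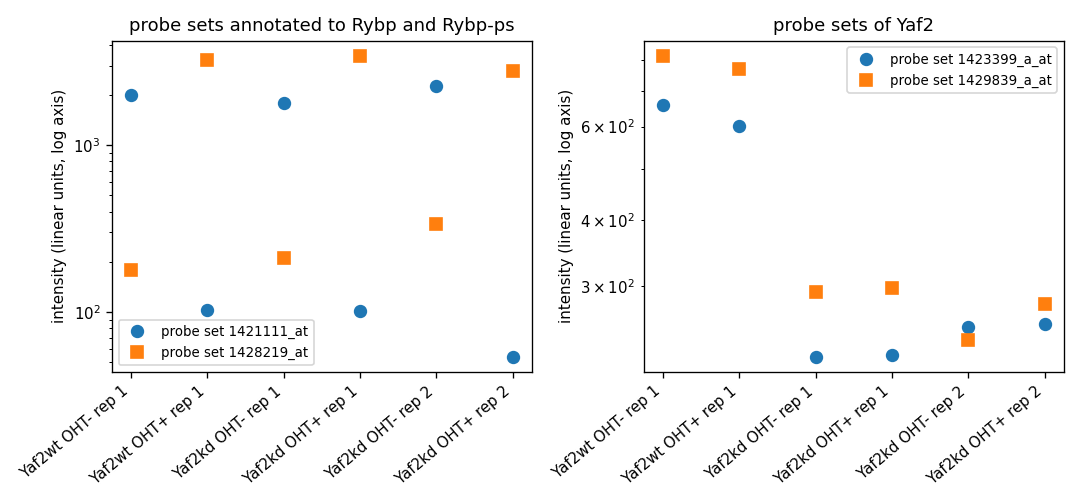
Intensity (log axis) of each probe set annotated to Rybp and Rybp-ps (left) and to Yaf2 (right) on each of the 6 arrays, with 1 circle and 1 square per array for the 2 probe sets of each panel. The Rybp probe sets change places between OHT- and OHT+ arrays in every clone, and both Yaf2 probe sets are lower on the 4 Yaf2kd arrays than on the 2 Yaf2wt arrays.

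The OHT effect over the 3 clones asks what the treatment meant to deplete Rybp does in these cells. Over all 18194 genes limma called 0 genes (lowest adjusted p 0.242), with 1531 at an unadjusted p under 0.05 where 909.7 are expected by chance. With the 40% of genes of lowest signal left out it called 38, of which 36 rose and 2 fell. With an intensity trend it called 60, of which 49 rose and 11 fell, and 26 genes were in both sets. Genes of germ cells and meiosis were the largest group of the fixed lists among the 38. Slc25a31, an ADP/ATP carrier of the male germ line, rose by 2.42 ± 0.22 (log2 ± SE of the fit without dim genes), Tex11, a meiotic gene on the X chromosome, by 2.39 ± 0.21, and Syce1, a part of the synaptonemal complex, by 2.23 ± 0.12. Their adjusted p was 0.0107, 0.00902 and 0.00399 in that fit, and Tex11 is dim without OHT.

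The germline and meiosis list had 47 measured members, 36 of them higher and 11 lower with OHT, with a median of 0.81 (log2). Over all genes 0 members passed, and 21 rose when adjusted over the list alone. Of the 32 members of higher signal, 12 rose with the dim genes left out. Besides the 3 above these were the piRNA pathway genes Mael (1.77) and Piwil2 (1.36), the germ cell RNA-binding protein gene Dazl (1.59), the RNA helicase gene Ddx4 (1.48), the synaptonemal complex gene Sycp2 (1.46), the general transcription factor homologue Taf7l (1.92), the homeobox gene Rhox13 (1.98), Stk31 (1.34) and the oocyte transcription factor gene Figla (1.21). Mov10l1 (1.53), Sohlh2 (1.16), Stra8 (1.07), the retinoic-acid-induced gatekeeper of meiosis, and Tex19.1 (0.82) rose in the fit with an intensity trend. Asz1 was at 2.16 ± 0.89 and did not pass. Sycp2 and Asz1 are dim without OHT. As a list these genes rose by camera (adjusted p 8.7e-15; adjusted p = 0.0890 with an estimated correlation), and fry gave an adjusted p of 0.00569. Among the genes of higher signal, the median of the germline genes was 0.83 in clone 3031, 1.15 in clone 3086 and 1.05 in clone 3087. The median of the fibroblast markers was 0.21, 0.31 and 0.41 in the same order.

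**Figure D2:**
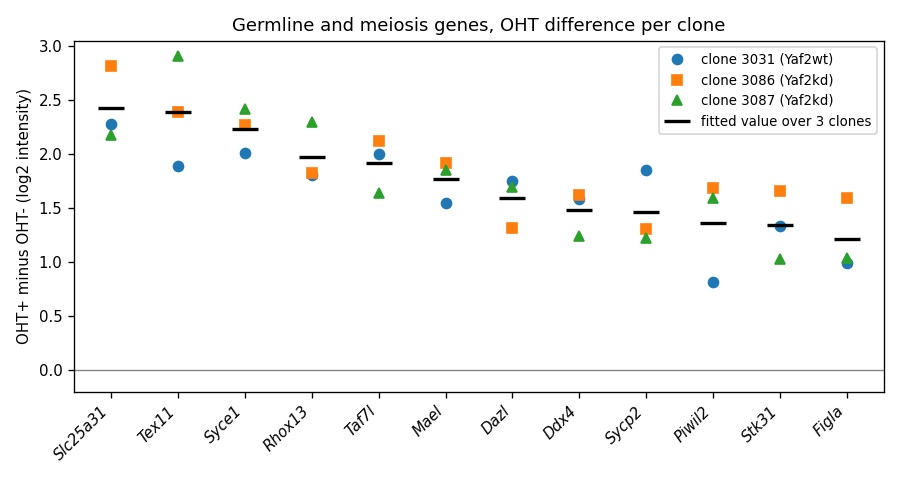
OHT+ minus OHT- difference (log2 intensity) of the 12 germline and meiosis genes that rose with the dim genes left out, with 1 point per clone and a bar for the fitted value. All 12 lie above 0 in each of the 3 clones.

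Other genes that rose with the dim genes left out, by log2, were AF067061 (3.82 ± 0.41, adjusted p 0.0194), the deubiquitinase gene Usp17la of the 2-cell-stage list (3.37 ± 0.23, adjusted p 0.00685), the cardiac myosin heavy chain gene Myh6 (2.03 ± 0.12), Crispld2 (1.94), the chemokine gene Cxcl14 (1.73), the adenylate cyclase gene Adcy7 (1.57), the retinoic-acid-binding protein gene Crabp1 (1.53), the glycogen phosphorylase gene Pygl (1.53), the signalling ligand gene Bmp4 (1.43 ± 0.11), Fbxo15, expressed in undifferentiated embryonic stem cells (1.36 ± 0.13), and the imprinted cell cycle inhibitor gene Cdkn1c (1.15). The 2 that fell were the cannabinoid receptor gene Cnr1 (-1.14 ± 0.14) and the enolase gene Eno3 (-0.81 ± 0.10). The sizes for AF067061, Usp17la, Myh6, Crispld2 and Cxcl14, which are dim without OHT, and for Cnr1, which is dim with it, are uncertain. In the fit with an intensity trend Myb (-0.87), the alpha-tubulin gene Tuba1a (-0.84) and the RNA-binding protein gene Igf2bp3 (-0.78) fell as well. Of the genes of higher signal, 30 were at least 2-fold higher in all 3 clones and 0 at least 2-fold lower. At any size, 38.5% moved the same way in all 3 clones, where chance gives 25%. Of these, 1982 were higher and 2225 lower. The largest differences over all genes, none of which passed there, were those of BC080696 (4.22), AF067061, Gm11544 (3.80), Serpinb1a (3.62) and 1700013H16Rik (3.52), and of 9130024F11Rik (-3.93), Rp1l1 (-3.68), Slc9a2 (-3.66), Ppp1r17 (-3.64) and 4930552N02Rik (-3.49). All of these are dim in at least 1 of the groups, so their sizes and order are uncertain.

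In this comparison 5 further lists shifted by camera. Fibroblast markers were higher (median 0.34, 26 of 33 higher, adjusted p 7.0e-05; adjusted p = 0.210 with an estimated correlation); 0 members passed, also when adjusted over the list alone, with Pdgfrb at 1.34 ± 0.27 and Col1a1 at 0.67 ± 0.21. Pluripotency genes were higher (median 0.16, 24 of 31 higher, adjusted p 0.00265; adjusted p = 0.210 with an estimated correlation). Fbxo15 was the 1 member that rose when adjusted over the list alone, Tcl1 (0.86) rose only in the fit with an intensity trend, and Klf4 was at 0.90 ± 0.24. Preimplantation and 2-cell-stage genes were higher (median 0.32, 17 of 26 higher, 2 risen when adjusted over the list alone, adjusted p 0.00609; adjusted p = 0.416 with an estimated correlation), with Ubtfl1 at 2.58 ± 0.65 and Tdpoz1 at -1.75 ± 0.45. Mesoderm and primitive streak genes were higher (median 0.24, 11 of 18 higher, adjusted p 0.0232; adjusted p = 0.416 with an estimated correlation, and 0.0601 with the clone as a block). Bmp4 was the 1 member that rose when adjusted over the list alone, Evx1 was at -2.43 ± 0.95 and Gsc at 1.82 ± 0.82. Epiblast and primed-state genes were lower (median -0.28, 12 of 14 lower, 0 passing when adjusted over the list alone, adjusted p 0.0187; adjusted p = 0.606 with an estimated correlation), with Sox3 at -1.14 ± 0.35, Otx2 at -0.78 ± 0.17, Sall2 at -0.70 ± 0.18 and Fgf8 at 1.90 ± 0.43. Of the genes named here Pdgfrb is dim without OHT, and Ubtfl1, Tdpoz1, Evx1, Gsc and Fgf8 are dim in both groups.

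The other 15 lists did not pass over all genes. With the dim genes left out the same 6 passed and 2 more did: trophectoderm and placenta genes were higher (median 0.52 over 14 members, adjusted p 5.95e-04; over all genes adjusted p = 0.416 with an estimated correlation) and neuroectoderm genes lower (median -0.17 over 9 members, adjusted p 0.0126; over all genes adjusted p = 0.615 with an estimated correlation). Over all genes, among the chromatin lists, PRC1 and PRC2 subunits had a median of -0.00486 and a mean of 0.0227 (camera higher, adjusted p 0.760), with Phc2 (0.63) and Bcor (0.61) rising in the fit with an intensity trend and Bmi1 at -0.59 ± 0.21. Polycomb-bound developmental regulators had a median of -0.0477 (adjusted p 0.633), with Foxc2 at 2.56 ± 0.86 and Bmp4 the 1 of 79 members that passed when adjusted over the list alone. Only 19 of these 79 members were of higher signal. Their median was 0.00241, and camera with the dim genes left out gave an adjusted p of 0.939. For the dim members a change could be hidden by noise. Over all genes the DNA and H3K9 methylation machinery had a median of -0.0089 and a mean of 0.0324 (camera higher, adjusted p 0.802), with Dnmt3l at 0.42 ± 0.11. Among the lineage lists, trophectoderm and placenta genes had a median of 0.0746 (adjusted p 0.0789, 4 risen when adjusted over the list alone, among them Bmp4 and Rhox9), primitive endoderm genes 0.00753 (mean -0.0632, camera higher, 0.703, with Ttr at -2.39 ± 0.33 as the 1 member that passed when adjusted over the list alone) and neuroectoderm genes -0.0622 (0.196, with Sox1 at -1.09 ± 0.24). Interferon-response genes had a median of 0.0513 (adjusted p 0.638), with Ifit1 at 2.38 ± 0.26 as the 1 member that passed when adjusted over the list alone, and imprinted genes 0.0296 (0.633, with 2 members passing when adjusted over the list alone, Cdkn1c higher and Nnat lower). The other medians and adjusted p were 0.0784 and 0.413 for p53 targets, -0.13 and 0.181 for sterol biosynthesis, 0.039 and 0.703 for cell cycle, 0.00775 and 0.919 for X- and Y-linked genes, 0.0449 and 0.124 for hypoxia and glycolysis, 0.0639 and 0.802 for stress response (mean -0.0568, camera lower), and 0.005 and 0.802 for control genes (mean -0.0226, camera lower); in these 7 lists 0 members passed when adjusted over the list alone. Foxc2, Ttr and Ifit1 are dim in both groups and Sox1 is dim with OHT.

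The 38 calls depended on single arrays: they became 4 without the Yaf2wt OHT+, the Yaf2wt OHT- or the first Yaf2kd OHT+ array, 15 and 22 without the first and the second Yaf2kd OHT- array, and 1 without the second Yaf2kd OHT+ array. They became 64 with the clone as a block, 4 without clone 3031, 27 without clone 3086 and 62 without clone 3087.

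**Figure D3:**
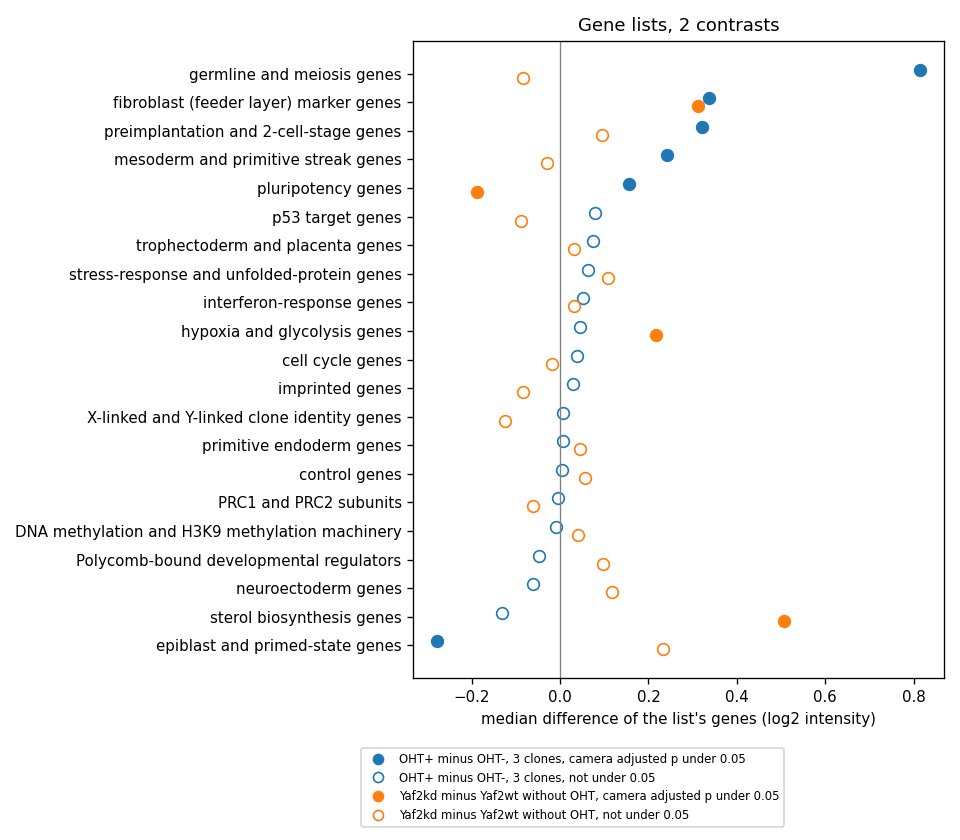
Median log2 difference of each of the 21 gene lists for OHT+ minus OHT- over 3 clones and for Yaf2kd minus Yaf2wt without OHT; filled points have a camera adjusted p under 0.05 at a preset correlation, and none of them keeps it with an estimated correlation. The germline list (0.81) lies highest for OHT, and the sterol list (0.51) highest for Yaf2kd.

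In the Yaf2kd cells alone, the OHT effect asks what the treatment does where Yaf2 is reduced, with 2 arrays against 2. Over all genes limma called 0 genes (1235 at an unadjusted p under 0.05). With the dim genes left out 4 rose: Usp17la (3.03 ± 0.19, adjusted p 0.0176), Tex11 (2.64 ± 0.22), Syce1 (2.34 ± 0.15) and Myh6 (2.15 ± 0.16). With an intensity trend 9 rose, namely Usp17la, Tex11, Syce1, Crabp1, Ddx4, Fbxo15, Mael, Piwil2 and AU015836. The germline list rose here too (median 0.86, 37 of 47 higher, 16 risen when adjusted over the list alone, camera adjusted p 9.0e-14, and 0.230 with an estimated correlation). All Yaf2kd arrays are also in the comparison over the 3 clones, so shared genes and lists are not an independent repetition. With dim genes left out and the clone as a block, a combination chosen after seeing the data, 72 genes rose and 9 fell, among the latter the neural transcription factor genes Sox3 (-1.60) and Sox1 (-1.29) and the receptor gene Cnr1 (-1.31). That fit leaves fewer residual degrees of freedom than the 4-group fit. The residuals of arrays from the same Yaf2kd clone correlated only weakly (r 0.12 over the genes of higher signal). Usp17la, Tex11 and Myh6 are dim without OHT and Sox1 and Cnr1 with it, so their sizes are uncertain.

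The same other 5 lists passed camera in the Yaf2kd cells. Epiblast genes were lower (median -0.43, adjusted p 0.00813; adjusted p = 0.635 with an estimated correlation). Pluripotency genes were higher (0.22, adjusted p 0.00813; adjusted p = 0.474 with an estimated correlation), with Fbxo15 at 1.27 ± 0.19. Fibroblast markers were higher (0.32, adjusted p 0.00146; adjusted p = 0.474 with an estimated correlation), with Pdgfrb at 1.41 ± 0.38. Preimplantation genes were higher (0.39, adjusted p 0.0338; adjusted p = 0.635 with an estimated correlation), as were mesoderm genes (0.40, adjusted p 0.0349; adjusted p = 0.568 with an estimated correlation, and 0.0775 with the clone as a block), with Fgf8 at 2.41 ± 0.35. Pdgfrb is dim without OHT and Fgf8 in both groups. Among the 6 lists, 2 were left without the second Yaf2kd OHT+ array. With the dim genes left out trophectoderm genes (higher, adjusted p 0.00141; over all genes adjusted p = 0.635 with an estimated correlation) and neuroectoderm genes (lower, adjusted p 0.00824; over all genes adjusted p = 0.678 with an estimated correlation) passed as well. The largest differences that did not pass were 5830403F22Rik (4.25), Lcn2 (4.19), BC080696 (4.14), Pcp4 (3.90) and AF067061 (3.89), and Rp1l1 (-4.48), Gm19395 (-4.10), Cfap97d1 (-3.89), Ube2d2b (-3.87) and Cts7 (-3.83), all dim in at least 1 of the groups. The calls with dim genes left out were 0 without either Yaf2kd OHT- array or the second OHT+ array and 1 without the first OHT+ array.

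In the Yaf2wt clone the effect of OHT where Yaf2 is intact rests on 1 array against 1, with no replicate, so a test has to borrow its spread from the Yaf2kd groups. The 10 highest genes were BC080696 (4.37), Usp17la (4.04), AF067061 (3.67), Gm20767 (2.91), Slc25a31 (2.28), Syce1 (2.01), Taf7l (2.00), 3110040M04Rik (1.93), Tex11 (1.89) and Sycp2 (1.85), of which 5 are in the germline list. The 10 lowest were Cdh10 (-1.61), Camk2d (-1.54), Ftx (-1.24), Thap2 (-1.23), Insm1 (-1.21), Pou5f2 (-1.20), Kif5a (-1.19), Tmem38a (-1.17), Dclk2 (-1.14) and Mocos (-1.12). The sizes and ranks of BC080696, Usp17la, AF067061, Gm20767, 3110040M04Rik and Sycp2, dim without OHT, and of Cdh10 and Tmem38a, dim with it, are uncertain. The germline list had a median of 0.51 (35 of 47 higher), above all of 10000 random lists of the same size and similar signal. Pluripotency genes had a median of 0.12 (percentile 100), trophectoderm genes 0.35 (percentile 99.97), fibroblast markers 0.18 (percentile 99.95) and imprinted genes 0.15 (percentile 99.86). Of the other lists called over the 3 clones, preimplantation genes were at percentile 99.16, mesoderm genes at 72.88 and epiblast genes at 7.33. With the spread pooled from the Yaf2kd groups, limma called 0 genes (966 at an unadjusted p under 0.05) and, with the dim genes left out, only Usp17la (adjusted p 0.0449).

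The Yaf2 effect without OHT asks how the knockdown cells differ in the absence of the treatment. It compares 2 Yaf2kd clones with 1 Yaf2wt clone, so knockdown and clone cannot be told apart. Sterol biosynthesis genes were higher in the Yaf2kd cells (median 0.51, 19 of 20 higher, adjusted p 1.2e-05; adjusted p = 0.547 with an estimated correlation), with the enzyme genes Hmgcs1 at 0.89 ± 0.28 and Msmo1 at 0.82 ± 0.28. Fibroblast markers were higher (median 0.31, 26 of 33 higher, adjusted p 0.00441; adjusted p = 0.547 with an estimated correlation). The median was 0.33 for the 25 markers of higher signal and -0.26 for the 8 dim ones, to which Lum (2.78 ± 0.36) belongs. Hypoxia and glycolysis genes were higher (median 0.22, 22 of 25 higher, adjusted p 0.0230; adjusted p = 0.547 with an estimated correlation), with Car9, dim in the Yaf2wt cells, at 0.80 ± 0.26. Pluripotency genes were lower (median -0.19, 26 of 31 lower, adjusted p 0.00441; adjusted p = 0.547 with an estimated correlation), with Tbx3 at -0.75 ± 0.35. In these 4 lists 0 members passed when adjusted over the list alone. Over all genes limma called 0 genes (1001 at an unadjusted p under 0.05), and it called 0 with the dim genes left out (432) and 0 with an intensity trend. By chance 909.7 would be expected at such a p over all genes and 545.8 with the dim genes left out, so 432 falls below chance. The largest differences were Acsm1 (5.32), 9130015A21Rik (5.01), Lrp1b (4.98), AY702102 (4.95) and 4933406G16Rik (4.89), and 4930532I03Rik (-4.84), Gm5148 (-4.64), Dlx1as (-4.28), Ifi204 (-4.19) and Styk1 (-4.08), all below the dim limit. Without the first Yaf2kd OHT- array 2 of the 4 lists were left.

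With OHT, the Yaf2kd cells again had higher sterol biosynthesis genes (median 0.44, 20 of 20 higher, adjusted p 3.9e-05; adjusted p = 0.655 with an estimated correlation), with Fdps at 0.90 ± 0.32 and Mvk at 0.76 ± 0.25. Fibroblast markers were higher (median 0.34, adjusted p 2.5e-04; adjusted p = 0.556 with an estimated correlation), with S100a4 at 1.08 ± 0.55. Trophectoderm genes (median 0.36, adjusted p 0.0215) and hypoxia genes (0.17, adjusted p 0.0335) were higher, and pluripotency genes (-0.12, adjusted p 0.0325) and X- and Y-linked clone identity genes (-0.21, 10 of 10 lower, adjusted p 0.0335) were lower. Each of these 4 had adjusted p = 0.556 with an estimated correlation. Klf4 was at -0.62 ± 0.42 and Xist, the RNA of the inactive X chromosome, at -0.79 ± 0.19. The same clones are compared as without OHT, so a difference between clones recurs here. Lists shared by the 2 comparisons are therefore not an independent repetition. In all 6 lists 0 members passed when adjusted over the list alone. Over all genes limma called 0 genes (929 at an unadjusted p under 0.05), and 0 with the dim genes left out (682) or an intensity trend. The largest differences were Hectd2os (5.98), 4933407I05Rik (5.44), 4930528G23Rik (4.74), 5330439B14Rik (4.72) and Ctla2b (4.67), and Omt2a (-5.23), Robo2 (-4.72), Pramel18 (-4.50), Ces2b (-4.29) and B020011L13Rik (-4.12), all below the dim limit. Without either of the Yaf2kd OHT+ arrays 2 of the 6 lists were left.

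The combined loss sets the 2 Yaf2kd OHT+ arrays against the lone Yaf2wt OHT- array. It is the Yaf2 effect without OHT plus the OHT effect in Yaf2kd cells. Lists shared with those comparisons are therefore not an independent repetition. Germline genes were higher (median 0.66, 34 of 47 higher, 12 risen and 1 fallen when adjusted over the list alone, adjusted p 1.7e-07; adjusted p = 0.337 with an estimated correlation; fry adjusted p 0.0144). With an intensity trend 4 genes rose, each with an adjusted p of 0.0447, namely Syce1 (2.20), Crabp1 (2.07), Mael (1.95) and Ddx4 (1.64). Fibroblast markers (median 0.64, adjusted p 1.7e-07; adjusted p = 0.337 with an estimated correlation), mesoderm genes (0.88, 0.00224; adjusted p = 0.347 with an estimated correlation) and trophectoderm genes (0.48, 0.00182; adjusted p = 0.347 with an estimated correlation) were higher. So were sterol genes (0.40, 9.4e-04; adjusted p = 0.680 with an estimated correlation), hypoxia genes (0.34, 9.4e-04; adjusted p = 0.350 with an estimated correlation) and preimplantation genes (0.43, 0.00449; adjusted p = 0.640 with an estimated correlation). Msmo1 was at 0.76 ± 0.28, Ndrg1 at 1.21 ± 0.48, Pdgfrb at 1.51 ± 0.46 and Usp17la at 2.92 ± 0.27; the last 2 are dim on the control array, so their sizes are uncertain. Over all genes limma called 0 genes (1271 at an unadjusted p under 0.05), and 0 with the dim genes left out (915). The largest differences were 5330439B14Rik (5.81), Asz1 (5.59), Nnmt (5.11), Nim1k (5.09) and Gm11544 (4.98), and Rp1l1 (-5.32), Qrfpr (-4.68), Ceacam14 (-4.48), Prl3c1 (-4.28) and Pcdhb4 (-4.20), all below the dim limit.

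Whether OHT acts differently in Yaf2kd and Yaf2wt cells was tested as the difference of the 2 OHT effects. No list passed over all genes, and the germline list had a median of 0.13 (adjusted p 0.794). Limma called 0 genes (833 at an unadjusted p under 0.05), and 0 with the dim genes left out (200), with an intensity trend or with the clone as a block. By chance 909.7 would be expected at such a p over all genes and 545.8 with the dim genes left out, so 833 and 200 both fall below chance. Sox3 was at -1.40 ± 0.38 and Fgf8, dim in every group, at 1.54 ± 0.61. The largest differences were Hectd2os (8.24), Fscn2 (7.66), Hao2 (6.71), Styk1 (6.70) and Uchl4 (6.49), and Omt2a (-7.83), Smpx (-7.09), Krtap16-3 (-6.91), B130034C11Rik (-6.80) and 1700065D16Rik (-6.71). All lie below the dim limit, so their sizes and order are uncertain. Krtap16-3 turns to 0.70 without probe sets of the _x_at or _s_at kind, and Sox3 to 0.47 with the mean of its probe sets.

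Across genes, the OHT differences of the clones correlated weakly. Pearson's r was 0.0532 (Spearman's rho 0.132) for clones 3031 and 3086, 0.0697 (0.148) for clones 3031 and 3087 and 0.0527 (0.110) for clones 3086 and 3087. Over the 10916 genes of higher signal r was 0.377, 0.384 and 0.293 in the same order. Genes are not independent replicates, so no p-value is given for these 3 relations.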

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

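The splits of the arrays, the tests of explanations for the 3 patterns that follow them and the fit on probe sets outside the gene table were chosen only after the result was seen.

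Among 2603 probe sets of higher signal that stand for no single gene, limma called 6 for the OHT effect over the 3 clones, 5 higher and 1 lower, with 230 at an unadjusted p under 0.05. These data are outside the gene comparisons, and the 6 include both Rybp probe sets. All 6 are annotated to several symbols. Those not annotated to Rybp rose by 4.16, 3.83, 3.54 and 3.46 (log2, limma adjusted p 0.0105 to 0.0202). These rises are about as large as the largest among the called genes. The sizes of 3.83 and 3.46 are uncertain, since the signal without OHT is dim. For epiblast and primed-state genes, the OHT effect differed between Yaf2kd and Yaf2wt cells in camera with the dim genes left out (adjusted p 0.00107, median difference -0.21 over 10 members). That call was absent over all genes (adjusted p 0.756), and it gave an adjusted p = 0.898 with an estimated correlation. Sox3 had the largest difference, at -0.20 in clone 3031, -1.31 in clone 3086 and -1.90 in clone 3087, but its difference of -1.40 turns to 0.47 with the mean of its probe sets. By the mean of the Yaf2kd clones 8 of the 10 members were more negative than in clone 3031. Of these, Nodal, Otx2 and Pou3f1 were less negative in clone 3086 than in clone 3031, so their share in the count rests on clone 3087.

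The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Over all genes the real split called 0 genes, as did the other splits, so 10 of 10 gave a result as large. With the dim genes left out the real split called 38 genes and the highest other 1, with an intensity trend 60 and 1, and for lists by camera 6 and 4. In these 3 results 1 split, the real one, was as large. The splits ignore which arrays share a clone, and most put both arrays of a clone on the same side. Among the even fewer others with 1 array of each clone per side, the highest results were 0, 0 and 1.

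The Rybp probe sets moved in opposite directions with OHT (-4.61, of uncertain size as its OHT+ signal is dim, and 3.75 in log2). Exchanged OHT labels in 1 or 2 clones are argued against, since 0 clones departed from the direction that both probe sets and the median of the germline list had in the others. Signal of the pseudogene Rybp-ps in the probe set that rose cannot be told apart from transcript of Rybp itself, since 0 further probe sets are annotated to Rybp-ps alone. A biological reading, in which the depleted allele still gives a transcript that only the probe set that rose detects, may also hold and was not tested, since the part of the gene each probe set covers is not known here.

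Germline genes were higher with OHT in all 3 clones. RNA of feeder fibroblasts as the whole cause was tested by setting the germline genes against fibroblast markers. The median of the germline genes exceeded that of the 9 fibroblast markers of no higher signal by 0.47 (log2, 95% interval 0.0482 to 1.01). It exceeded that of all 25 markers of higher signal, the form tried first, by 0.61 (0.19 to 1.11). Both intervals come from resampling genes and hold no spread between clones. In clones 3031, 3086 and 3087 the germline medians were 0.83, 1.15 and 1.05, and those of the 25 markers 0.21, 0.31 and 0.41. The germline genes thus rose more than the markers. How much of each marker's signal comes from the stem cells is not known here, and such signal would make its rise smaller. The comparison therefore cannot decide about feeder RNA. Noise of dim probe sets is argued against, since 23 of the 32 germline genes of higher signal were higher in all 3 clones, where the 18.0% of other such genes with that pattern would give 5.76. An effect of 4-hydroxytamoxifen itself cannot be told apart from the loss of Rybp, since 0 OHT+ arrays kept the signal of the Rybp probe set that fell. Loss of Rybp is the biological explanation the design names, and it remains a hypothesis here.

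Fibroblast markers were higher with OHT (median 0.34), and the cultures may have held feeder cells. A larger share of feeder cells was tested by whether markers of low signal moved more than the others. The difference was -0.0429 (log2, 95% interval from resampling genes -0.42 to 0.32), which decides nothing. In order of signal, the most abundant markers were Fn1 at -0.0264, Lgals1 at 0.14, Ccn1 at -0.38, Acta2 at 0.31 and Tagln at -0.26. Next came Ccn2 at 0.0107 and Vim at 0.17. However, embryonic stem cells express some of these, and their high baseline would hide a small share. A change in the share of feeder cells therefore cannot be told apart from a change within the stem cells, and the biological effect of the treatment stays untested.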

How the results depend on the processing

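The pseudocount and all second choices combined with dim genes left out were tests chosen only after the result was seen; the other alternatives were planned. Over all genes limma called 0 genes in each comparison. The OHT effect over the 3 clones kept 0 under each array or clone left out and changed to 38 with dim genes left out and 60 with an intensity trend; the OHT effect in Yaf2kd cells changed to 4 and 9, and the combined loss to 4 with the trend. Leaving out dim genes tests fewer genes and removes the noisiest; why the trend adds calls was not tested further.

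With dim genes left out, the 38 calls over 3 clones became 64 with the clone as a block (37 of the 38 kept), 19 with the mean of all probe sets, 126 with an intensity trend, 59 with a pseudocount of 16, 20 as the mean of both OHT contrasts of the 4-group fit, 4 without clone 3031, 27 without clone 3086, 62 without clone 3087 and 0 without moderation; each array left out gave 1 to 22, and the 12 germline calls became 1 to 10. The 4 calls in Yaf2kd cells became 81 with the block, 42 with the trend, 20 with the pseudocount, 0 with the mean of probe sets and 0 without moderation; each array left out gave 0 to 4. Why calls were lost when arrays were left out was not tested. The number of arrays alone does not account for it, since the 38 calls rose to 62 without clone 3087.

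Of the lists called, 6 over the 3 clones, 6 in Yaf2kd cells, 4 and 6 for the Yaf2 effect without and with OHT and 7 for the combined loss, 0 held with an estimated correlation in any of these comparisons. With fry 1 list held over the 3 clones, 1 in the combined loss and 0 in the others. Each array left out gave 4 to 6, 2 to 6, 2 to 4, 2 to 6 and 7. With dim genes left out the counts were 8, 8, 5, 7 and 10, with 0 lists lost, and the difference of OHT effects went from 0 to 1. Over all alternatives the calls of single lists were kept 166 times and lost 90 times, and 0 turned in direction.

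The Rybp difference (-4.61) is 3.75 for the other probe set and -0.43 for the mean of both. The Yaf2wt germline median of 0.51 is 0.83 with dim genes left out, and the clone correlations of 0.0532, 0.0697 and 0.0527 are 0.377, 0.384 and 0.293. Tfcp2l1 reversed with the mean of all probe sets, to -0.54 over the 3 clones, -0.88 in Yaf2kd cells and 1.01 for Yaf2 without OHT, and Slc7a2 to -0.10 over the 3 clones. Sox3 reversed to 0.47 with that mean and Krtap16-3 to 0.70 without _x_at and _s_at probe sets, both for the difference of OHT effects. Yaf2, near 0 under OHT, reversed to -0.0521 without the second Yaf2kd OHT- array (arrays left out gave -0.0521 to 0.12) and to -0.0322 without clone 3087 over the 3 clones, and to -0.0264 without that array in Yaf2kd cells (-0.0264 to 0.27). The causes of these were not tested. Of the values of named genes under all alternatives, 3189 kept their direction and side of the threshold, 91 newly passed and 9 reversed. Since the main fit over all genes called 0 genes, no named gene could lose a call. The 3189 values kept are thus ones that passed in neither fit. The clone as a random block for the Yaf2 effects and the combined loss was not run, since its correlation could not be estimated from 6 arrays. Signal over background limits genes of low intensity, whose replicate spread was 0.70 against 0.16 (log2).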

Other observations

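The genes named next were chosen after their values were seen, whereas no test was chosen after the result was seen. All values are the OHT effect over the 3 clones in log2, with the same direction in each clone. In the limma fit with the dim genes left out, genes in no list that rose include the T-cell kinase gene Zap70 (1.34), AU015836 (1.31), the general transcription factor homologue Gtf2a1l (1.15, dim without OHT), Catsperz, part of a sperm ion channel complex (1.12), the cationic amino acid transporter gene Slc7a2 (1.06, but -0.10 with the mean of its probe sets), the acyltransferase gene Gpat2 (1.03), the helicase gene Ddx43 (0.92) and the retinol-binding protein gene Rbp4 (0.75). In the fit with an intensity trend the fatty-acid-binding protein gene Fabp5 (0.96), the transglutaminase gene Tgm2 (1.04) and the phosphatase gene Dusp9 (0.85) rose, and the chromatin gene Bend3 (-0.72), the endocytic receptor gene Lrp2 (-0.73) and the peptide hormone gene Apela (-0.61) fell.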
